A study of Mus musculus with 10 samples.

How the data were processed

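Messenger RNA was sequenced from mouse brain tissue in 10 libraries. Per the labels, 3 libraries came from naive mice, 3 from mice that had a temporary occlusion of the middle cerebral artery (MCAO), and 4 from mice that had the same operation and were given Cu9S8-SNAP. The series text places the tissue 3 days after the operation. The labels name no sham operation and no injection of a carrier alone. Surgery thus cannot be told apart from the occlusion, nor the injection from Cu9S8-SNAP. Total RNA was extracted with a Transzol kit and libraries were made with an Illumina mRNA kit, per the labels' protocols. The genome build mm9 and the program StringTie are named in the submitters' processing notes, with no role and no version. The aligner, the read counter, the strandedness of the kit and the program behind the deposited tests are not given in the sources used here. The labels do not say whether the libraries of a group came from separate animals. The p-values of single genes given here therefore measure only the spread between these samples, which may be technical.

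The authors deposited 3 tables, one for each pair of groups, and each table holds only the genes that its authors selected. Every listed gene had an absolute log2 fold change above 1 and an unadjusted p-value under 0.05 in the deposited columns. The expression values are deposited on a log2 scale. Each value equalled log2 of a whole read count times one factor per library, plus a pseudocount of 1, for 100% of values within a tolerance of 0.001 of a whole read, and the factor and the values of a gene were identical wherever a library appeared in more than one table. The library factors lay between 0.883 and 1.09. The group means and the log2 fold changes in the deposited tables equalled the mean of the log2 values and their difference. The deposited p-value columns hold an unadjusted p-value and a false discovery rate (FDR) per gene. The ratio of the deposited p-value to its FDR gave the most whole ranks for 33871 tested genes in the comparison of MCAO with naive, 34355 in that of treated MCAO with MCAO, and 33979 in that of treated MCAO with naive (whole for 90.2%, 59.98% and 78.8% of listed genes, so the second number is the least certain), and the deposited adjustment was of the Benjamini-Hochberg kind over more genes than are listed. Values per library are given below as normalized counts, the read count times the library factor, with the SD between libraries.

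The tables listed 4271, 1694 and 3733 genes in that order and 6450 different genes together, of which 3046 had values in all 10 libraries. The depth of the libraries cannot be had from tables of selected genes. Over the genes listed for each group, the recovered reads came to between 6435478 and 6926483 per naive library (5786 genes), 5189563 and 6251183 per MCAO library (5245 genes), and 3864348 and 4898753 per treated library (4915 genes). These sums are not library depths. A gene at 0 reads in every library of a group was given the floor of 3 reads per library, and its fold is written as a lower bound. The floor covers counting error only, since reads without molecular identifiers are not independent molecules.

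The design, the gene lists, the rule for naming genes and the alternatives were set before the data were examined. The design had assumed FPKM values for all genes. Because the tables instead held log2 normalized counts of selected genes, the clause written for that case was used: a gene counts as called, and as higher or lower, when the FDR in the authors' deposited table is under 0.05, and limma was fitted over the selected genes only. The fit (limma 3.58.1 in R 4.3.3, with statmod 1.5.0) used the log2 values of all 10 libraries with 3 group means, moderated variances with a trend and robust estimation, and genes with a normalized count of at least 10 in at least 3 libraries, in place of the FPKM filter. Limma p-values were adjusted by the Benjamini-Hochberg method over the number of genes recovered from the deposited ranks. Every unlisted gene was taken as unchanged, which is conservative for the adjustment. The moderated variances rest on the selected genes, and selection by p-value may have favoured genes of low spread. The design had foreseen no count of tested genes. The number recovered from the ranks was used for this adjustment only. In simulated data for 4322 genes with an SD of 0.3 on the log2 scale, limma recovered 99%, 97% and 96% of genes changed by 2 on the log2 scale and 44%, 57% and 51% of those changed by 1, for MCAO against naive, treated MCAO against MCAO and treated MCAO against naive, with 0, 0 and 1 false calls. That SD is below the spread measured in MCAO and treated libraries, so a second simulation, added after the results had been seen, took the median SD of each group over 1885 genes (0.26 in naive, 0.39 in MCAO and 0.61 in treated libraries). In it limma recovered 97%, 65% and 61% of genes changed by 2 and 24%, 0% and 0% of those changed by 1, with 0 false calls. Both simulations fitted 2 groups only, not all 10 libraries, and changed 100 genes by each amount. With more genes changed the adjustment would be less strict.

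The lists of genes comprised 18 of cell types, 19 of processes and 2 of quality. Some lists held an older and a newer name of the same gene, and such names count as separate members. Examples are Chil3 and Chi3l3, Drd1 and Drd1a, Gucy1a1 and Gucy1a3, and Gucy1b1 and Gucy1b3. For each list with at least 3 called members, a two-sided Fisher exact test set its higher and lower called members against those of all other called genes of the same table, with Benjamini-Hochberg adjustment over the lists tested. Since the tables hold only selected genes, such a test compares directions within the called genes and is no enrichment against all genes. It counts genes as independent and measures no spread between libraries, so genes that move together can make its p-value too small. Members that are not listed were either not expressed, not changed by enough, too variable for an unadjusted p under 0.05, or not tested. These cases cannot be told from each other. Pathway names (KEGG) in the deposited tables were tested in the same way, a test added after the data had been seen. A further 6 lists of genes of brain regions were written after the largest changes had been seen. The named genes were, per comparison, the 4 called genes with the largest increase and the 4 with the largest decrease among genes whose libraries did not overlap between groups and whose mean normalized count reached 100 in the higher group (in place of a minimum in FPKM), the 2 called members with the largest absolute change of each list with at least 3 called members, and Gfap, Hmox1, Nos2, Mt1, Il1b, Tnf, Snap25, P2ry12, Cldn5 and S100a8. Genes named outside that rule are said to have been chosen after their values were seen. Gene symbols and Ensembl gene identifiers are those of the files. GENCODE vM21, of another genome build, was used only to look up which genes overlap each other, and 6435 of the 6450 identifiers were found in it, so no coordinates are given.

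Principal components were computed from the log2 values of the 3046 genes with values in all libraries. For the genes that moved back toward the naive level, 20 simulations of a treated group with no effect against the same MCAO libraries gave the overlap, covariance and correlation that the shared libraries produce alone. These draw the error of each gene on its own, so 100 further simulations, added after the results had been seen, kept shifts shared by many genes: deviations of whole libraries from their group mean were shuffled between MCAO and treated libraries, with random signs. Alternatives were an unfiltered fit, a pseudocount of 0.1, fits of 2 groups only, array quality weights, each library left out in turn, and, added after the data had been seen, limma-voom on the recovered reads, reads with no library factor, other adjustments for the unlisted genes, and the omission of the brain region genes. The figures were drawn with matplotlib 3.10.9, and the other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Reads of near-identical genes (Serpina3m, Saa3, Ftl1, Hbb-bt, Ly6c1, Chil3, Mt1 and Mt2 among those named) may have been split between copies by the counting, so their values are uncertain, as are those of overlapping and antisense genes such as Hotairm1, since no strand setting is given.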

Results

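Gene expression was measured by mRNA sequencing in mouse brain tissue, in 3 libraries of naive brains, 3 libraries after temporary occlusion of the middle cerebral artery (MCAO), a model of ischemic stroke, and 4 libraries after the same operation with Cu9S8-SNAP, a copper sulfide material injected as the treatment. The deposited tables held the genes that the authors had selected in each comparison, as log2 normalized counts, and 3046 genes had values in all 10 libraries. Recovered reads over the listed genes ranged from 3864348 in a treated library to 6926483 in a naive library, and the depth of the whole libraries is unknown. Over the 3046 genes the first principal component, with 66.2% of the variance, separated naive from MCAO libraries, and the second, with 12.2%, separated MCAO from treated libraries. These genes had been selected for differences between the same groups, so a separation by group is largely built in. The 4 treated libraries lay at 55.1%, 68.4%, 99.99% and 96.0% of the way from the naive to the MCAO mean on the first component (mean 79.9% ± 21.7, SD, n = 4), so treated replicates 1 and 2 lay nearer to the naive libraries than treated replicates 3 and 4. The median SD of a gene between libraries was 0.24 on the log2 scale in naive, 0.38 in MCAO and 0.63 in treated libraries, over 1513 genes with values in all of them.

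**Figure D1:**
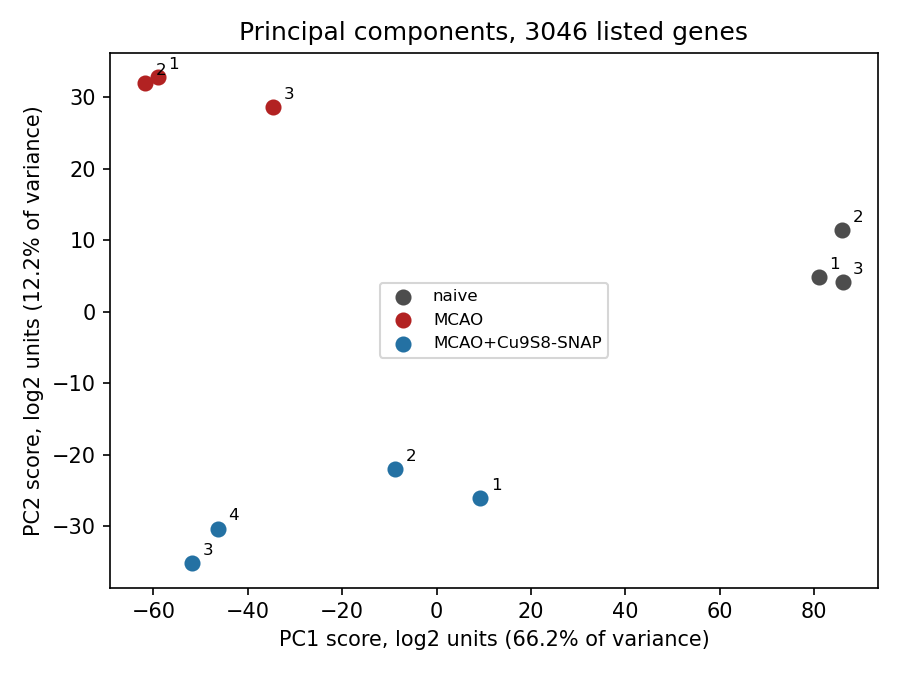
Scores of the 10 libraries on the first (horizontal) and second (vertical) principal component of the log2 normalized counts of 3046 listed genes, in log2 units, with each point a library coloured by group and numbered by replicate. The first component held 66.2% of the variance, and the treated libraries spread from 55.1% to 99.99% of the way from the naive to the MCAO mean.

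The comparison of MCAO with naive brains asked what the operation, surgery included, changed. At 3 days, genes of inflammation, reactive glia and tissue remodelling were higher in MCAO brains, and genes of neurons and synapses were lower. Gfap (ENSMUSG00000020932), the intermediate filament of astrocytes, went from 10236 ± 4119 normalized counts in naive brains (SD, n = 3) to 67913 ± 6970 in MCAO brains (n = 3), and Lcn2 (ENSMUSG00000026822), a secreted protein of reactive astrocytes and neutrophils, rose from 18.3 ± 8.75 to 5348 ± 789. Nrgn (ENSMUSG00000053310), a calmodulin-binding protein of excitatory neurons, fell from 39655 ± 11928 to 9091 ± 4111. In the authors' deposited table, 3549 of the 4271 listed genes passed an FDR of 0.05, 2316 of them higher and 1233 lower. The limma fit over the listed genes called 1604 genes, 1597 of them among those called by the authors.

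Of the 4 largest increases under the naming rule, 3 were of genes with no reads in any naive library. Mmp3 (ENSMUSG00000043613), a protease that degrades extracellular matrix, was at least 555-fold higher in MCAO brains, where it reached 1701 ± 735 normalized counts. The acute-phase gene Saa3 (ENSMUSG00000040026) was at least 310-fold higher, and the protease inhibitor gene Serpina3m (ENSMUSG00000079012) at least 190-fold higher. Tgm1 (ENSMUSG00000022218), a protein-crosslinking transglutaminase, rose by 9.02 ± 0.45 on the log2 scale (limma SE, adjusted p = 1.39e-07). Among the largest decreases, Gkn3 (ENSMUSG00000030048) fell from 157 ± 48.0 to 5.21 ± 4.69 normalized counts, and Hrh1 (ENSMUSG00000053004), a histamine receptor, from 308 ± 181 to 13.1 ± 1.83. Sh3rf2 (ENSMUSG00000057719) fell from 265 ± 253 to 13.5 ± 7.07. H1fx (ENSMUSG00000044927), a linker histone gene, had 789 ± 90.9 normalized counts in naive libraries and no reads in MCAO libraries, at least 272-fold lower, but in treated libraries it had no reads in replicates 1 and 3, 532 counts in replicate 2 and 760 in replicate 4, and limma did not call it (adjusted p = 0.0592).

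All 18 reactive astrocyte genes rose in the authors' deposited table (18 adjusted over the list alone), and their direction differed from that of the other called genes (Fisher exact test, adjusted p = 0.00395 over 29 lists). Among them were Lcn2 and Timp1, an inhibitor of matrix proteases (7.26 ± 0.56 on the log2 scale, limma SE). Of 19 cytokine and chemokine genes 18 rose (18 adjusted over the list alone, adjusted p = 0.00395), among them Ccl2, which recruits monocytes (8.89 ± 0.78), and Cxcl2, which recruits neutrophils and had no reads in naive libraries (at least 138-fold higher). Tnf rose by 5.87 ± 0.73 and Il1b by 4.55 ± 0.77. All 11 complement genes rose (11 adjusted over the list alone, adjusted p = 0.0397), with the receptor genes C3ar1 (4.82 ± 0.46) and C5ar1 (4.75 ± 0.75) changing most. Of 18 genes of activated microglia and macrophages 13 rose (13 adjusted over the list alone, adjusted p = 0.0255), led by the secreted Spp1 (6.46 ± 0.75) and the lectin Lgals3 (from 35.7 ± 1.74 to 2527 ± 1105 normalized counts). Of 11 names in the list of infiltrating monocytes and macrophages 10 rose (10 adjusted over the list alone, adjusted p = 0.0486), with Arg1 (7.18 ± 1.11) and Chil3 (8.52 ± 1.34) changing most. The name left over, Chi3l3, is an older name of Chil3. By limma calls none of these lists passed the test of direction, with 18 reactive astrocyte genes (adjusted p = 0.0918 over 23 lists) and 17 cytokine and chemokine genes (adjusted p = 0.123) called higher. All 13 genes of activated microglia and macrophages that limma called were higher, with an unadjusted Fisher exact p of 0.0829. Lists with up to 13 limma calls, such as those of complement and of monocytes, could thus not pass by rising. P2ry12, a receptor of resting microglia, fell from 726 ± 329 to 225 ± 52.4 normalized counts and was called in the authors' deposited table, while limma did not call it (adjusted p = 0.0636).

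Antioxidant and matrix genes also moved toward higher values. In the authors' deposited table, 10 of 16 antioxidant genes rose (10 adjusted over the list alone, Fisher exact adjusted p = 0.0486), including Hmox1, the inducible heme oxygenase, from 220 ± 3.04 to 13013 ± 9568 normalized counts, and the thioredoxin reductase gene Txnrd1 (1.76 ± 0.32 on the log2 scale, limma SE). Limma called 2 of these 10, too few for the test of direction. Of 14 matrix genes 10 rose (10 adjusted over the list alone, adjusted p = 0.0486), among them Mmp3 and the macrophage protease gene Mmp12, which had no reads in naive libraries and was at least 118-fold higher. By the 8 matrix genes that limma called, all higher, the adjusted p was 0.455, and 8 could not pass by rising (unadjusted Fisher exact p = 0.217). By the authors' calls, 8 called members that all rose gave an unadjusted Fisher exact p of 0.0570. Lists with up to 8 called members could thus not pass by rising. Several other lists held called genes that all rose but did not pass the test of direction. They were 8 of 13 neutrophil genes (9 adjusted over the list alone, adjusted p = 0.110), with the chemokine receptor Cxcr2 at 7.18 ± 0.89, and 9 of 12 genes of Toll-like receptor signaling and adhesion (9 adjusted over the list alone, adjusted p = 0.0772), with the endothelial selectin genes Selp and Sele at least 126-fold and 72.3-fold higher. Likewise 6 of 18 copper and metallothionein genes (6 adjusted over the list alone, adjusted p = 0.150) rose, among them the metalloreductase Steap4 (4.33 ± 0.41) and the metallothioneins Mt2 (2.55 ± 0.46) and Mt1 (2.14 ± 0.39). Of 13 endothelial barrier genes 5 rose (5 adjusted over the list alone, adjusted p = 0.206), including the adhesion genes Pecam1 (2.71 ± 0.37) and Cdh5 (2.66 ± 0.47), and the tight junction gene Cldn5 stood at 1.09 ± 0.34 with a limma adjusted p of 0.0903. Of 18 interferon-stimulated genes 0 were called (0 adjusted over the list alone).

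Neuronal genes moved the other way. In the authors' deposited table, 7 of 10 excitatory neuron genes fell (7 adjusted over the list alone, Fisher exact adjusted p = 0.00395), including Nrgn and the transcription factor gene Neurod6, from 3083 ± 696 to 567 ± 149 normalized counts. Of 11 names in the list of striatal spiny neurons 8 fell (10 adjusted over the list alone, adjusted p = 0.00303), among them the phosphodiesterase gene Pde10a (−2.93 ± 0.65 on the log2 scale, limma SE) and the receptor gene Gpr6 (−3.59 ± 0.90). Drd1a, an older name of Drd1, was counted beside it. Of 14 synaptic genes 8 fell (9 adjusted over the list alone, adjusted p = 0.00303), including the scaffold gene Homer1 (−1.69 ± 0.37) and the glutamate receptor gene Grin2a (−1.55 ± 0.35), and 6 of 12 general neuron genes fell (6 adjusted over the list alone, adjusted p = 0.00843), including Nefl, a neurofilament gene, and Rbfox3, which encodes the nuclear marker NeuN. Snap25, a vesicle fusion gene, fell by 1.22 ± 0.31. The immediate early genes were mixed, with Fos higher (2.62 ± 0.53) and Egr4 lower (−2.70 ± 0.46). The mean log2 value of 5 striatal genes ran from 9.27 to 11.3 among naive libraries. In the region lists, 4 of 15 hypothalamus and 2 of 9 cerebellum genes were listed as lower in MCAO and 0 as higher. Of 11 midbrain genes 1 was listed as higher, and of 7 raphe genes 1 as higher and 1 as lower. By limma calls, the lists that passed numbered 3 in place of 11, and all 3 were neuronal: striatal spiny neurons (6 lower, adjusted p = 0.00181), synaptic genes (5 lower, adjusted p = 0.00440) and excitatory neurons (4 lower, adjusted p = 0.0142). Of the limma calls 79.2% were higher, so falling lists could pass with fewer members than rising ones. These list calls changed with the library left out: 0 lists passed without naive replicate 2 or 3 or MCAO replicate 1 or 2, 1 without naive replicate 1 and 5 without MCAO replicate 3. Leaving out a single library lowered the limma count from 1604 to 1015, 905 and 871 without naive replicates 1, 2 and 3, and to 681 and 847 without MCAO replicates 1 and 2. Of the 73 genes named by the rule, limma called 66, and 48 of these stayed called whichever library was left out.

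**Figure D2:**
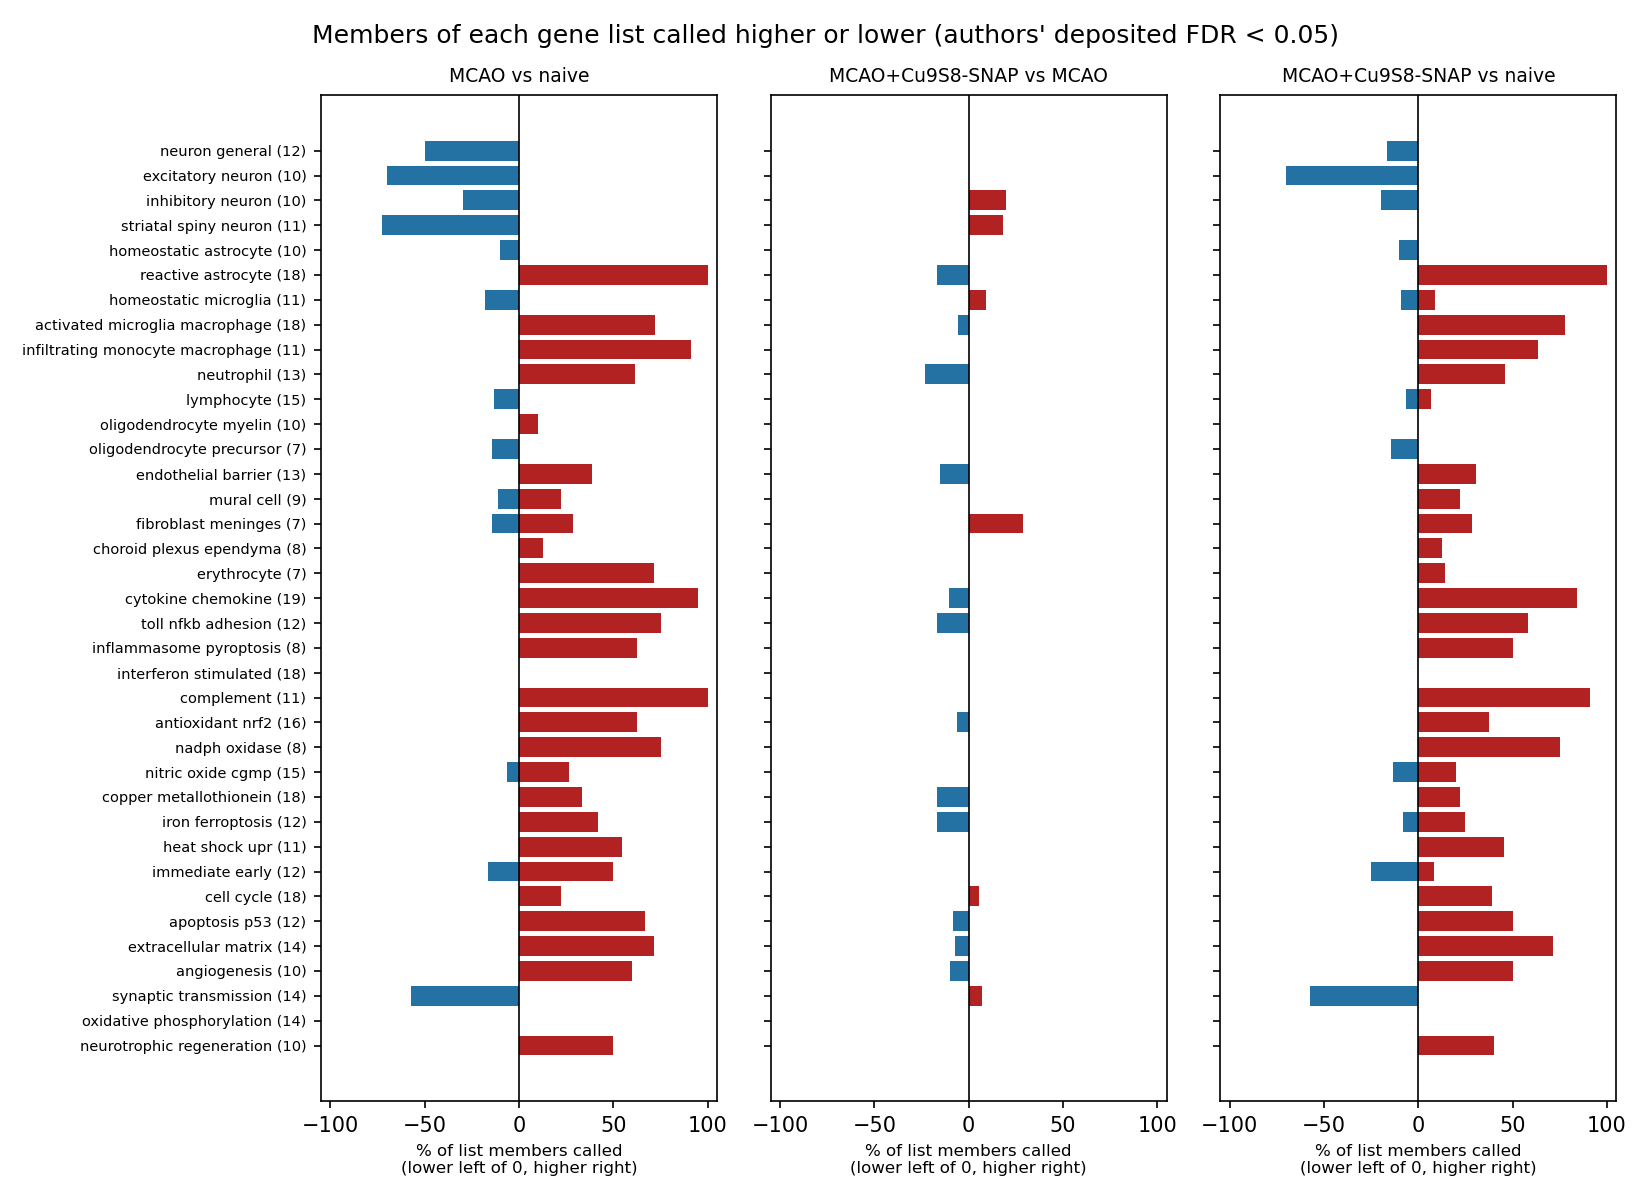
Percent of the members of each gene list that were called higher (right of 0, red) or lower (left of 0, blue) by the authors' deposited FDR, with a panel for each comparison and the number of members in parentheses. In MCAO against naive brains all 18 reactive astrocyte genes were higher and 8 of 14 synaptic genes lower, while treated against untreated MCAO brains had no more than 3 called members in any list drawn.

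The comparison of treated with untreated MCAO brains asked what differed after the operation with an injection of Cu9S8-SNAP. No group injected with a carrier alone is named. Single genes of cytokines and neutrophils were among the largest decreases in treated brains, and transcription factor genes of deep brain regions among the largest increases. No list fixed beforehand passed the test of direction, but none could have. The 3 lists tested had 3 called members each, all lower, which gave a Fisher exact p of 0.279. In a list written later, 3 called members that were all higher gave 0.0634. Il6 (ENSMUSG00000025746), an inflammatory cytokine, had 744 ± 432 normalized counts in MCAO libraries (SD, n = 3) and 77.3 ± 44.7 in treated libraries (n = 4). Csf3 (ENSMUSG00000038067), the growth factor for neutrophils, had 147 ± 25.4 and 21.0 ± 17.4, and S100a9 (ENSMUSG00000056071), an abundant neutrophil protein, 1127 ± 325 and 195 ± 112. Otp (ENSMUSG00000021685), a transcription factor gene of the hypothalamus, rose from 7.99 ± 2.67 to 308 ± 134. In the authors' deposited table, 653 of 1694 listed genes passed an FDR of 0.05, 261 higher and 392 lower.

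The number of calls depended on the fit and on its adjustment. Limma called 2 genes in the same comparison, while 1247 listed genes had an unadjusted limma p under 0.05. The 2 were Otp (5.02 ± 0.54 on the log2 scale, limma SE, adjusted p = 0.00717) and Hotairm1 (ENSMUSG00000087658), a noncoding RNA of the Hoxa cluster, named after its values were seen, which had no reads in MCAO libraries and was at least 11.03-fold higher in treated libraries (adjusted p = 0.0217). The limma adjustment counts every unlisted gene as unchanged. It called 411 genes when all unlisted genes with a deposited p under 0.05 were ranked ahead of the listed ones. That is a high estimate, and the number of such genes rests on the recovered ranks. Limma called 503 genes with array quality weights and 1219 when adjusted over the listed genes only. The last count is nearly fixed in advance, because these genes were listed for their p-value in the same comparison. Other settings lowered the count, to 1 with only the libraries of the 2 groups or without MCAO replicate 2, and to 0 by limma-voom (1174 at an unadjusted p under 0.05), without MCAO replicate 3 (1062) and without treated replicate 2 (1138), and it was 9 without treated replicate 1. The call of Otp was lost in those 3 settings with 0 calls (adjusted p = 0.202, 0.158 and 0.0509), with log2 changes of 5.11, 4.76 and 4.91. Simulated data had the spread measured in each group, 100 genes changed by each amount, and the libraries of these 2 groups only. In them limma recovered 65% of genes changed by 2 on the log2 scale and 0% of those changed by 1. Its adjusted p-values for the other named genes lay between 0.244 and 1.00 with equal weights, while with array quality weights 6 more of the 15 named genes passed.

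The other increases named by the rule, which leaves out genes whose libraries overlap between groups, were also transcription factor genes of developing or deep brain regions. Pax5 (ENSMUSG00000014030) had a log2 change of 3.60 ± 0.65 (limma SE), Foxb1 (ENSMUSG00000059246) 3.31 ± 0.68 and Lhx1 (ENSMUSG00000018698) 3.30 ± 0.79. The other large decrease was growth hormone, Gh (ENSMUSG00000020713), at −4.29 ± 1.40, which varied from 1.96 to 196 normalized counts among naive libraries. Of 18 reactive astrocyte genes 3 fell (3 adjusted over the list alone), among them Steap4 (−1.67 ± 0.38) and the surface protein gene Cd109 (−1.68 ± 0.34), and 0 rose. Of 13 neutrophil genes 3 fell (6 adjusted over the list alone), including S100a9 (−2.72 ± 0.60) and the collagenase gene Mmp8 (−3.84 ± 0.89). Of 18 copper and metallothionein genes 3 fell (3 adjusted over the list alone), including Cp, which encodes the copper-carrying ferroxidase ceruloplasmin (−1.78 ± 0.41), and the copper pump gene Atp7a (−1.96 ± 0.39). None of these 3 lists passed the test of direction (Fisher exact adjusted p = 0.279 for each), which their size had fixed in advance. Of 19 cytokine and chemokine genes 2 fell (3 adjusted over the list alone), Il6 and Ptgs2, too few for the test. Of 8 choroid plexus and ependyma genes, 5 were listed as lower and 0 as higher, with 0 called (5 adjusted over the list alone). Tnf was not listed as different, with 107 ± 64.6 normalized counts in MCAO and 104 ± 60.3 in treated libraries. Il1b stood at −2.40 ± 0.72 and Nos2, the inducible nitric oxide synthase, at −1.25 ± 0.58, and neither passed the FDR in the authors' deposited table (0.178 and 0.310). Gfap was not listed as different and had 97570 ± 29897 normalized counts in treated libraries.

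Genes of deep brain regions, listed after these changes had been seen, were higher in treated libraries, and those named here were chosen after their values were seen. Of 50 genes of the midbrain, raphe, hindbrain, hypothalamus and cerebellum, 30 were listed as higher than in MCAO and 0 as lower, and 15 were called higher in the authors' deposited table. A sixth list, of 9 genes of the thalamus, went the other way, with 0 listed as higher, 2 as lower and 1 called lower. The hypothalamic peptide gene Hcrt had 10.5 ± 10.8 normalized counts in MCAO and 808 ± 883 in treated libraries, and Tph2, an enzyme of serotonin synthesis in the raphe, 44.1 ± 16.1 and 536 ± 397. Hoxb3, a gene of the hindbrain, had no reads in any naive or MCAO library or in treated replicate 1, and 125, 63.1 and 86.5 normalized counts in treated replicates 2, 3 and 4. The dopamine synthesis gene Th had 1678 ± 388 normalized counts in treated libraries, against 171 ± 17.2 in naive and 356 ± 465 in MCAO libraries. These values accompany every difference between treated and MCAO libraries given here.

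**Figure D3:**
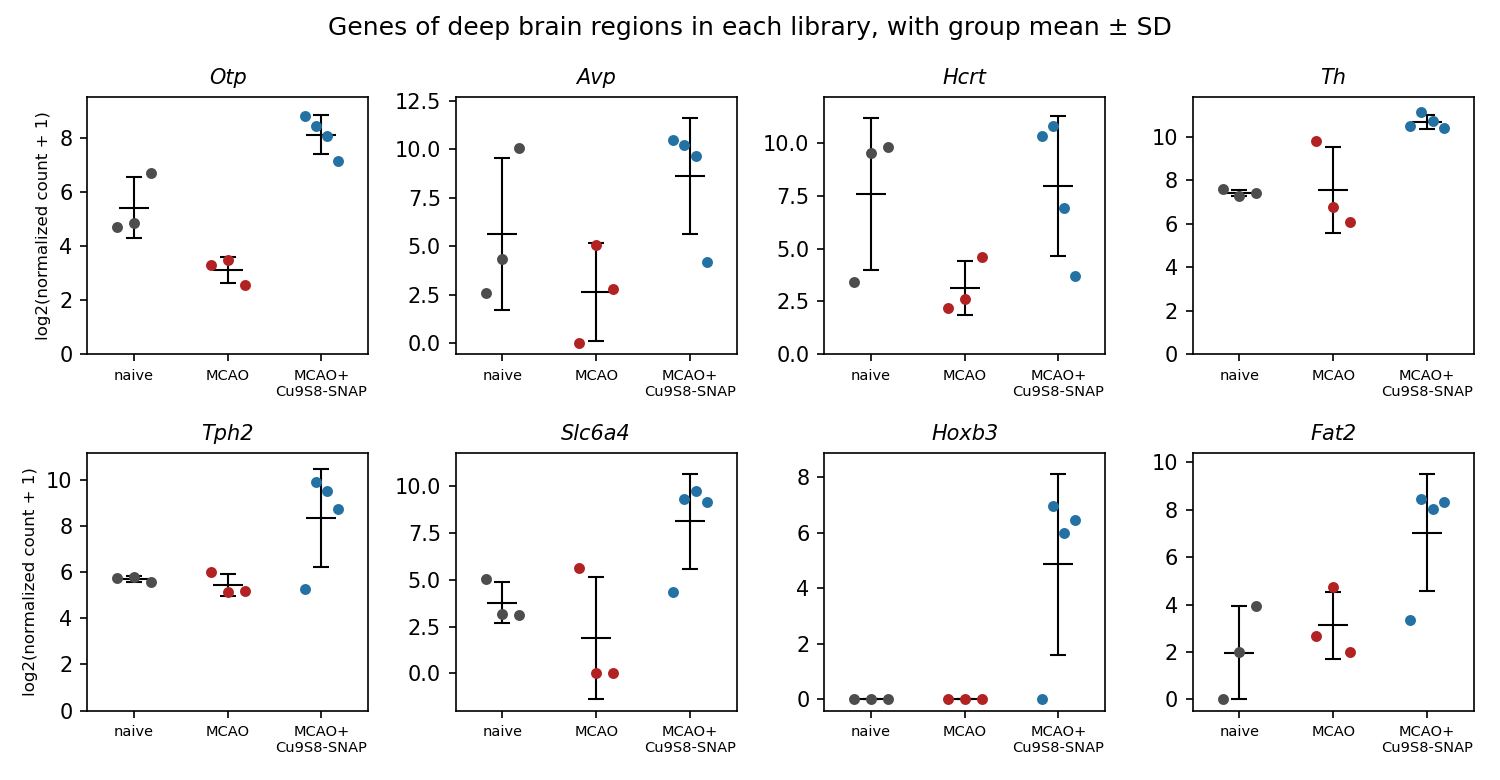
Log2 of the normalized count plus 1 (vertical) of 8 genes of deep brain regions in each library (points) of the 3 groups (horizontal), with bars for the group mean and SD. Hoxb3 had no reads in any naive or MCAO library, and the lowest Otp value of a treated library, 141 normalized counts, was above the highest of an MCAO library, 10.1.

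The comparison of treated MCAO brains with naive brains asked how far treated brains still differed from uninjured ones. Reactive astrocyte, microglia and cytokine genes were higher and synaptic and excitatory neuron genes lower than in naive brains. Of the 50 genes of deep brain regions, 31 were also listed as higher than in naive brains and 0 as lower, including 9 of 11 midbrain genes (7 called by limma), and these values accompany the other differences from naive brains. Of 9 thalamus genes, which are not among those 50, 1 was called higher and 2 lower. Gfap rose from 10236 ± 4119 normalized counts (SD, n = 3) to 97570 ± 29897 (n = 4), Hmox1 from 220 ± 3.04 to 8321 ± 7292, and Lcn2 from 18.3 ± 8.75 to 3299 ± 2581. In the authors' deposited table, 2633 of 3733 listed genes passed an FDR of 0.05, 1694 higher and 939 lower, and limma called 982, of which 976 were among the authors' calls. The largest increases were Tgm1 (8.75 ± 0.42 on the log2 scale, limma SE), Saa3 (at least 150-fold higher), Mmp3 (at least 151-fold higher) and Serpina3m (at least 85.1-fold higher). The largest decreases were the potassium channel subunit gene Kcnv1 (ENSMUSG00000022342, −2.80 ± 0.49), the anoctamin gene Ano3 (ENSMUSG00000074968, −2.75 ± 0.49), the immunoglobulin heavy chain gene Ighg2c (ENSMUSG00000076612, −2.70 ± 0.60) and Ipcef1 (ENSMUSG00000064065, −2.60 ± 0.49).

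All 18 reactive astrocyte genes rose in treated against naive brains in the authors' deposited table (18 adjusted over the list alone, Fisher exact adjusted p = 0.00554 over 23 lists), as did 16 of 19 cytokine and chemokine genes (16 adjusted over the list alone, adjusted p = 0.00623). Ccl2 rose by 7.34 ± 0.73 on the log2 scale (limma SE), Tnf by 5.78 ± 0.68, and Il1rn, which encodes an antagonist of interleukin 1, by 6.41 ± 0.74. Of 18 genes of activated microglia and macrophages 14 rose (14 adjusted over the list alone, adjusted p = 0.0153), including Spp1 (5.10 ± 0.70) and Lgals3 (5.59 ± 0.54). Excitatory neuron genes fell in 7 of 10 (7 adjusted over the list alone, adjusted p = 0.00554), with Neurod6 at −2.19 ± 0.48 and Nrgn at −1.98 ± 0.38, and synaptic genes in 8 of 14 (8 adjusted over the list alone, adjusted p = 0.00554), with Homer1 at −2.30 ± 0.35. By limma calls the synaptic list alone passed (5 lower, adjusted p = 0.00606 over 18 lists), and 0 lists passed without naive replicate 1, 2 or 3, 2 without treated replicate 1 and 3 without treated replicate 2 or 4. The 16 reactive astrocyte genes that limma called were all higher, with an unadjusted Fisher exact p of 0.0535. No list had more limma calls, so none could pass by rising. In the authors' deposited table, 0 of 11 names in the list of striatal spiny neurons (0 adjusted over the list alone) and 2 of 12 general neuron genes (2 adjusted over the list alone) were called, both of the latter lower. The mean log2 value of 5 striatal genes ran from 8.43 to 10.7 among treated libraries. Against untreated MCAO brains, 3 striatal genes were listed as higher in treated brains and 0 as lower, with 2 called by the authors and 0 by limma. Of the general neuron genes 0 were listed there. The called genes were too few for the test of direction, so it stays open whether these lists as a whole differ from untreated MCAO brains. Complement genes (10 of 11 higher, 10 adjusted over the list alone, adjusted p = 0.0574) did not pass the test of direction. Nor did neutrophil genes (6 of 13 higher, 6 adjusted over the list alone, adjusted p = 0.156). Their 6 called members could not pass by rising (unadjusted Fisher exact p = 0.0949). P2ry12 fell by 2.02 ± 0.42. Limma did not call Snap25 (−1.10 ± 0.29, adjusted p = 0.0631), Il1b (2.16 ± 0.72, adjusted p = 0.156) or Cldn5 (1.15 ± 0.32, adjusted p = 0.0702), which the authors' deposited table had called. Leaving out a treated library moved the limma count from 982 to 1523 without replicate 2 and to 473 and 595 without replicates 3 and 4, and leaving out a naive library to 564, 456 and 455 without replicates 1, 2 and 3.

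**Figure D4:**
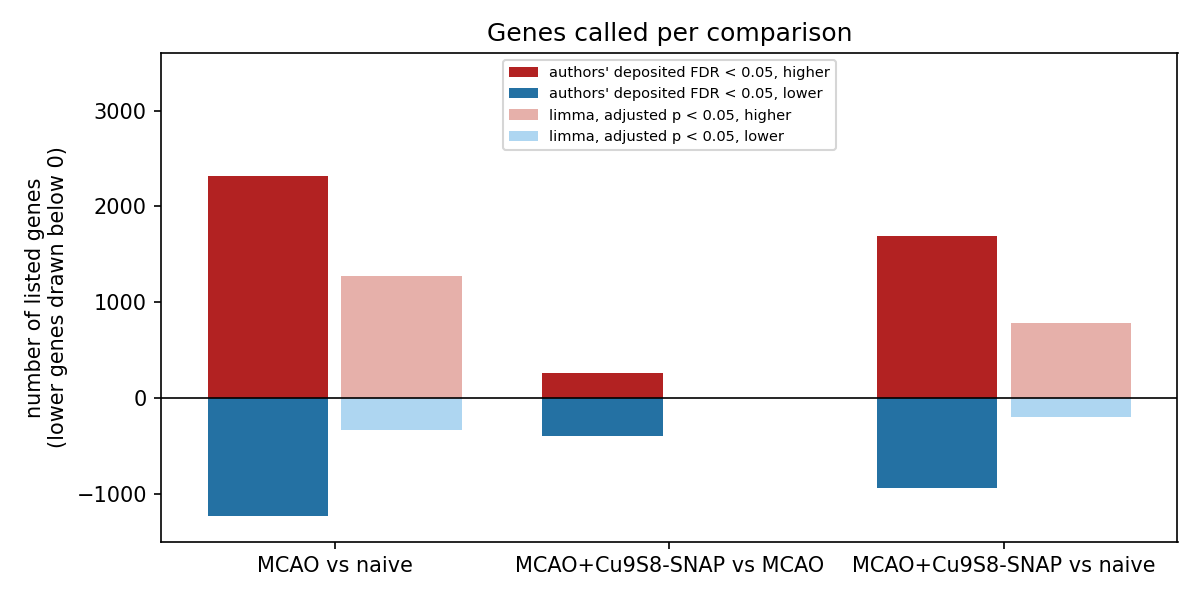
Number of listed genes called higher (above 0, red) and lower (below 0, blue) in each comparison, by the authors' deposited FDR (dark bars) and by limma over the listed genes (light bars). The authors' tables called 3549, 653 and 2633 genes and limma 1604, 2 and 982.

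Across the comparisons, genes that the operation had changed were set beside what the treatment changed. Of the genes called in MCAO against naive, 316 were also called in treated against untreated MCAO in the authors' deposited tables, and all 316 had the opposite direction, 218 higher with the operation and lower with treatment and 98 the reverse. Independent lists of these sizes would share 26.8 and 9.50 genes in those directions. They made up 8.90% of the genes called for the operation and 48.4% of those called for the treatment. Limma called 2 genes in both, Otp and Hotairm1, which were lower in MCAO than in naive brains and higher in treated brains. Neither is a member of the lists fixed beforehand. Because both comparisons use the same MCAO libraries, opposite directions arise without any effect. With limma p under 0.05 and a change over 2-fold in both, 543 genes with values in all libraries, listed in any table for treated brains, were found, 537 of them opposite, against a mean of 77.1 in 20 simulations of an ineffective treatment (range 54 to 87), of which 47.9 were opposite. The covariance of the log2 fold changes was −0.94, against −0.16 in the simulations. The 3 MCAO libraries are too few to be divided between the comparisons, so part of the excess may come from sharing them. Those simulations draw each gene on its own, and in 100 others that kept whole deviations of libraries from their group mean, over 2488 genes, 4 gave at least 543 genes in both (median 45, highest 723) and 14 a covariance as low.

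The genes of the operation were also followed into treated brains. Of the genes called for the operation in the authors' deposited tables, 1773 (49.96%) were also called in the same direction in treated against naive brains and 2 in the opposite one, and 1542 were not listed there. Both comparisons use the same naive libraries, so genes are shared without any link between operation and treatment. With limma p under 0.05 and a change over 2-fold in both, 1914 genes were shared, against a mean of 2707 in the 20 simulations of an ineffective treatment, which had values for every gene where the tables did not. In the 100 simulations with whole library deviations, 39 shared as few (range 1603 to 2260). The change was smaller in treated brains for 74.9% of the shared genes, and 24 of these 100 simulations gave as high a share (range 11.6% to 89.7%).

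**Figure D5:**
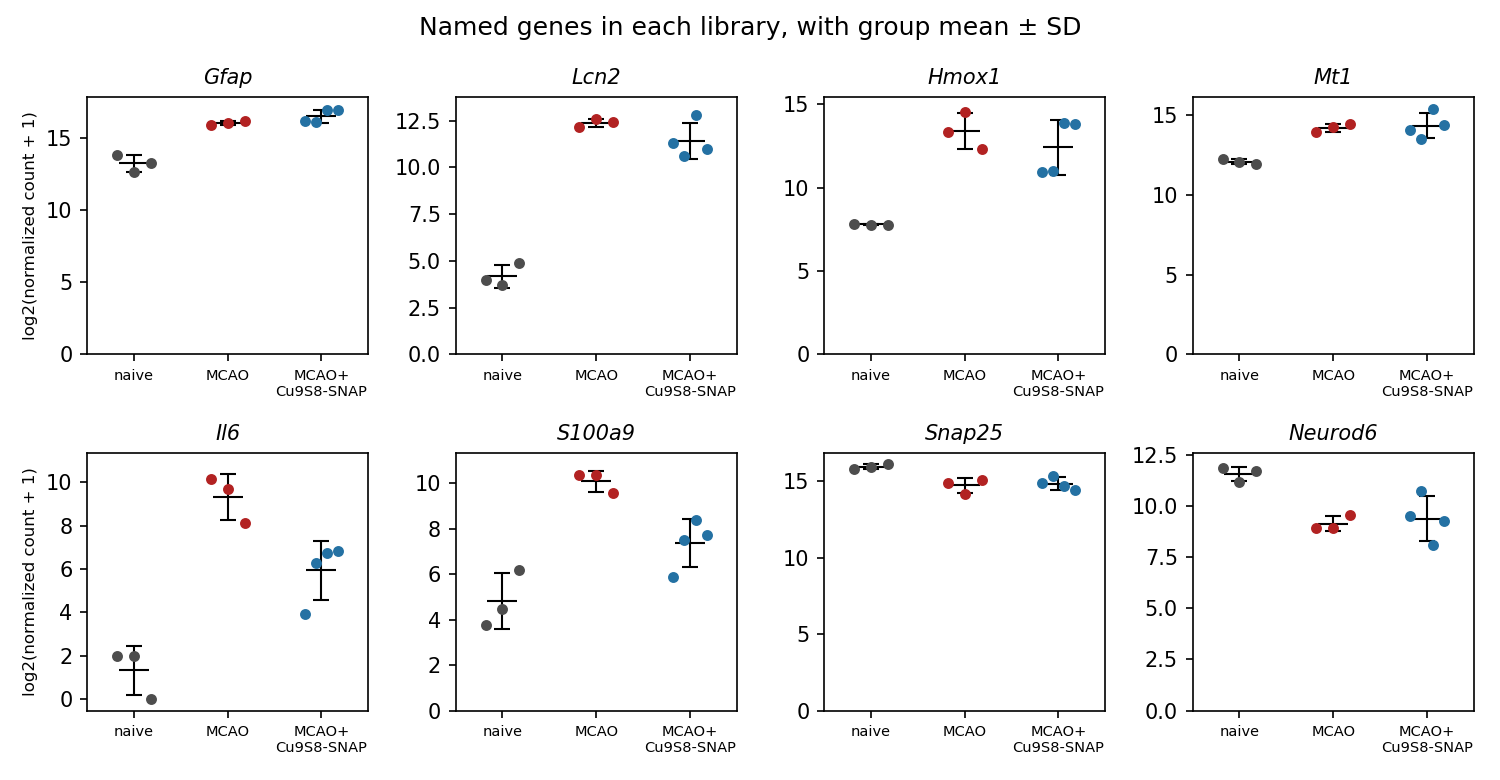
Log2 of the normalized count plus 1 (vertical) of 8 named genes in each library (points) of the 3 groups (horizontal), with bars for the group mean and SD. Il6 and S100a9 lay lower in all 4 treated than in all 3 MCAO libraries, while Gfap did not.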

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

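The tests of the extent of deep brain tissue and those of a return to the naive level were chosen only after the result had been seen. In the treated group, 6 of 124 values (94 genes, and scores of lists and libraries) had a library whose gap to its nearest neighbour took a larger share of the range of the 4 libraries, on the log2 scale, than Dixon's critical value at 95% allows, where chance gives about 1 in 20, here 6.2. For Pax5 this share was 0.938, with 41.6 normalized counts in treated replicate 1 and between 183 and 201 in the other libraries. For Lhx1 it was 0.864, with 243 counts in treated replicate 2 and between 149 and 160 in the others. For Dcn, a proteoglycan gene of fibroblasts, it was 0.859, with 419 counts in treated replicate 1 and at least 1870 in the others. For Sele it was 0.925, with 27.4 counts in treated replicate 1 and at least 70.6 in the others. For Fmod it was 0.95, with 241 counts in treated replicate 3 and at least 445 in the others. For Sh3rf2 it was 0.865, with 174 counts in treated replicate 1 and at most 19.7 in the others.

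Genes of deep brain regions were higher in treated than in MCAO libraries. A return to the naive level is argued against for the 66.7% (20 of 30) of the members listed as higher than in MCAO that were also listed as higher than in naive brains, but it stays open for the other 10, of which 6 (Avp, Barhl1, Hcrt, Htr1a, Pcp2 and Pmch) were listed as lower in MCAO than in naive brains. A larger extent of deep brain tissue in the treated libraries may account for the pattern: all 15 called members (100%) were higher, in 4 of 5 lists (Fisher exact adjusted p = 0.0118 for the hypothalamus, 0.0378 for the cerebellum and 0.0634 for the raphe), in genes listed after the first of them had been seen, but a list of the thalamus, outside this test, had 2 of 9 genes listed as lower and 0 as higher. The regions differed between libraries, since treated replicate 1 had 459 normalized counts of Otp but no Hoxb3, 37.5 of Tph2 and 9.13 of Fat2, while treated replicate 4 had 86.5 of Hoxb3, 426 of Tph2 and 320 of Fat2 but 16.9 of the hypothalamic peptide gene Avp, and Hcrt ranged from 9.79 to 903 among naive libraries too. An induction of these genes by the treatment itself was not tested and stays open.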

How the results depend on the processing

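The limma-voom fit, the fit without library factors, the other adjustments for unlisted genes, the counts by unadjusted p and the omission of brain region genes were chosen only after the result had been seen. For MCAO against naive, treated against untreated MCAO and treated against naive, the authors' deposited tables called 3549, 653 and 2633 genes, and limma 1604, 2 and 982. The limma counts were 3477, 1219 and 3020 when adjusted over the listed genes only (selected by p, so nearly fixed in advance), 2737, 411 and 1999 when all unlisted genes with a deposited p under 0.05 were ranked first (a high estimate), 3511, 1247 and 3039 at an unadjusted p under 0.05, and 3080, 503 and 2689 with array quality weights. The first 3 sets differ from the limma counts only in the adjustment, and the weights gave treated replicates 1 and 2 the lowest weight (0.233 and 0.282). Limma-voom gave 2295, 0 and 540, and fits of 2 groups 2373, 1 and 762. Without the filter, with a pseudocount of 0.1 or without library factors each count stayed within 1.5 times its value. The authors' listing by unadjusted P held 1694 genes for treated against untreated MCAO.

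With single libraries left out, which lowers the number of samples, limma gave 681 to 1464 genes for MCAO against naive (1015, 905 and 871 without naive replicates 1, 2 and 3, 681 and 847 without MCAO replicates 1 and 2). For treated against untreated MCAO it gave 0 to 9 (0 without MCAO replicate 3 or treated replicate 2, 1 without MCAO replicate 2, 9 without treated replicate 1), with at least 785 genes at an unadjusted p under 0.05. For treated against naive it gave 455 to 1523 (564, 456 and 455 without naive replicates 1, 2 and 3, 473 and 595 without treated replicates 3 and 4, 1523 without treated replicate 2). Genes changed oppositely by operation and treatment numbered 316 by the authors' calls, 710 by their listing, 2 by limma, 305 with the filter and 312 without brain region genes. Among genes listed in both tables, those at a limma p under 0.05 in both numbered 507, and 323 to 494 with a library left out, lowest without MCAO replicate 1.

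Lists past the test of direction numbered 11, 0 (fixed by the size of the lists) and 5 by the authors' calls, and 9 for treated against naive by their listing. By limma calls they numbered 3 for MCAO against naive (6 with 2 groups, 7 with weights, 6 by voom, 0 to 5 with a library left out: 1 without naive replicate 1, 0 without naive replicates 2 and 3 and MCAO replicates 1 and 2, 5 without MCAO replicate 3). For treated against naive they numbered 1 (7 with weights, 3 by voom, 0 to 3 with a library left out: 0 without naive replicate 1, 2 or 3, 2 without treated replicate 1, 3 without replicates 2 and 4). In the main fit no list of that comparison had enough limma calls to pass by rising. Except where stated, the cause was not tested. The position of treated libraries on the first component stayed between 71.1% and 88.4% of the way to MCAO. Of the named genes, 48 of 66, 0 of 1 and 35 of 55 limma calls held whichever library was left out, and no direction turned in any setting run. Camera, rescaling to equal medians or upper quartiles, edgeR and DESeq2 were not run. The tables hold only selected genes, on which their scaling and spread would rest. The moderated variances of limma and limma-voom rest on the same selected genes. A 2-fold minimum is met by every listed gene, and limma's 2 calls for treated against untreated MCAO allow no list test. With whole-library depth unknown, limits for genes at 0 rest on 3 reads per library.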

Other observations

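The tests of dilution, of pathway names, of whole library deviations and of lists among the genes lowered by treatment were chosen only after the result had been seen. Other lists fixed before the data were examined held called genes but did not pass the test of direction in MCAO against naive brains. Of all called genes 65.3% were higher. All 6 called genes of the 11 of heat shock and unfolded proteins were higher (Fisher exact adjusted p = 0.150). Most changed were the stress transcription factor gene Atf3, from 27.4 ± 12.5 to 3432 ± 1406 normalized counts (SD, n = 3), and the small heat shock gene Hspb1, from 196 ± 15.4 to 4671 ± 1074. All 8 called genes of the 12 of apoptosis and p53 were higher (adjusted p = 0.110). Among them were the cell cycle inhibitor gene Cdkn1a, from 559 ± 126 to 9864 ± 759, and Gadd45b, from 443 ± 61.0 to 4438 ± 1580. The called genes of angiogenesis (6 of 10, adjusted p = 0.150), NADPH oxidase (6 of 8, adjusted p = 0.150) and the inflammasome (5 of 8, adjusted p = 0.206) were all higher. So were those of iron and ferroptosis (5 of 12, adjusted p = 0.206) and red blood cells (5 of 7, adjusted p = 0.206). The same held for regeneration (5 of 10, adjusted p = 0.206) and the cell cycle (4 of 18, adjusted p = 0.354). Examples were the vessel growth gene Angpt2 (from 55.9 ± 20.5 to 1186 ± 484), the oxidase gene Cybb (from 30.0 ± 16.7 to 694 ± 645), the inflammasome sensor gene Nlrp3 (from 30.1 ± 5.05 to 191 ± 55.2), the prostaglandin synthase gene Ptgs2 (from 327 ± 124 to 1963 ± 817), the heme synthesis gene Alas2 (from 175 ± 26.3 to 551 ± 49.9), the cytokine gene Lif (from 24.3 ± 7.09 to 1375 ± 515) and the replication gene Mcm3 (from 132 ± 8.07 to 574 ± 122). Genes of inhibitory neurons fell in 3 of 10 (adjusted p = 0.0934), including Cck and Pvalb. Lists with both directions were those of nitric oxide (4 higher, 1 lower, adjusted p = 0.741), immediate early genes (6 and 2, adjusted p = 0.775), mural cells (2 and 1, adjusted p = 1.00) and fibroblasts (2 and 1, adjusted p = 1.00). Fewer than 3 genes were called in the lists of resting astrocytes, resting microglia, lymphocytes, myelin, oligodendrocyte precursors, choroid plexus and interferon response, and 0 in those of oxidative phosphorylation, mitochondrial RNA and the sex chromosomes.

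By pathway names in the authors' deposited tables, the direction of called genes differed most for the glutamatergic synapse, with 8 higher and 30 lower in MCAO against naive brains (Fisher exact adjusted p = 1.04e-08 over 193 pathways) and 6 higher and 25 lower in treated against naive brains (adjusted p = 2.81e-08 over 176). All 49 called genes of TNF signaling were higher after the operation (adjusted p = 3.20e-06). In treated against untreated MCAO brains only neuroactive ligand and receptor genes passed, with 17 higher and 6 lower (adjusted p = 0.000993 over 12 pathways). Among the 8 neutrophil genes called higher after the operation, 6 were listed as lower with treatment, against 18.7% of all genes called higher (Fisher exact adjusted p = 0.0181 over 22 lists), but by the called genes alone the adjusted p was 0.355. Chosen after their values were seen, the inhibitory neuron genes Slc32a1 (from 1587 ± 468 to 4208 ± 1574 normalized counts) and Pvalb (from 1251 ± 674 to 3727 ± 1871) and the dopamine receptor gene Drd2 (from 215 ± 83.0 to 591 ± 252) were called higher in treated than in MCAO libraries in the authors' deposited table. Also chosen after its values were seen, the Y-linked gene Kdm5d had between 254 and 869 normalized counts in treated and between 781 and 1053 in naive libraries and was not called.

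Genes induced by the operation were lower in treated libraries. Over 508 genes at least 8-fold higher in MCAO, the median change with treatment was −1.06 on the log2 scale, but the library medians were −1.94 and −1.36 in treated replicates 1 and 2 and −0.24 and −0.32 in treated replicates 3 and 4, beside −0.50 in MCAO replicate 3. Chance from the shared MCAO libraries stays open: the 543 genes that changed in both comparisons lay above the highest of 20 simulations with independent genes (87), but 4 of 100 simulations that kept whole library deviations gave as many (highest 723). Dilution of injured tissue by other tissue, to a different extent in each library, may contribute, since the SD of the change over genes was 1.05 times what the errors of the genes give, or 1.37 times once library medians were removed, under the bound of 1.5, although the changes ran from −4.29 to 1.86 (5th to 95th percentile −2.60 to −0.06). A milder injury in some animals or an effect of Cu9S8-SNAP would give the same fall, so the test does not separate them.

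Some genes were expressed in part of the libraries of a group and near 0 in the rest, with 17 such genes among naive, 16 among MCAO and 50 among treated libraries, H1fx, Arg1 and Hcrt among the last. Reads assigned to an overlapping gene, as the source for the set, would raise the share that overlaps another gene in GENCODE vM21. That share was not raised, at 35 of 68 (51.5%), against 52.6% of the other genes (Fisher exact p = 0.903). With overlap so common, and no strand setting given, the test cannot exclude this source for the 35 genes that do overlap. Differences in tissue between libraries stay open for this pattern and were not tested.

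Other ways of dividing the same libraries were compared with the real groups by limma. For MCAO against naive, 1 of 10 splits, the real one, gave as many genes (2373, highest other 2, on genes selected on the real groups, and 187 against 1 on genes of the other tables), and the splits are too few for a share under 0.05. For treated against untreated MCAO, tested on genes of the other tables, 2 of 35 splits gave at least the 3 genes of the real split, so chance cannot be excluded. These genes were listed as different from naive in both MCAO and treated brains. That leaves out genes that treatment returned to near the naive level, so the low count of the real split does not decide the question. At an unadjusted p under 0.05, 8 of 35 splits gave at least the 201 genes of the real split (highest other 967). The split that set MCAO replicate 3 and treated replicates 1 and 2 apart gave 475 genes after adjustment, which points to a structure of the samples other than the groups. On the genes of its own table the real split gave 1 gene and the highest other split 17. For treated against naive, 1 of 35 splits, the real one, gave as many genes (762, highest other 325), but the genes had been selected on the real groups, so chance is not excluded by it, and on genes of the other tables the real split gave 145 genes and the split that set naive libraries and treated replicate 1 apart from the rest gave 155. Those genes were listed in both comparisons with MCAO, nearly all in opposite directions, which favours treated values near naive ones. That set does not decide the question either.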
